A study of Arabidopsis thaliana with 18 samples.

How the data were processed

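Polyadenylated RNA from leaves of 4-week-old Arabidopsis thaliana plants was sequenced in 18 libraries, 3 from each combination of 3 lines (wild type, phyA-211 and ein3eil1) with air or 6 hours of submergence. The series title names PHYA and the escape response to submergence, and the labels give line, condition and replicate number but not the ein3 and eil1 alleles or the origin of replicates. RNA was selected with oligo(dT) beads and copied to cDNA with random primers, per the labels' protocols, which do not state whether strand was kept, so reads of overlapping antisense genes cannot be told apart.

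The deposited table holds 1 value per gene and library, in TPM made by the authors. No header or label names this unit: it was inferred from the deposited TPM values, which have decimals, sum to between 996105 and 998620 per library, and have lowest nonzero values several times higher in short genes than in long ones. That quantile had medians over libraries of 0.213 TPM in genes of up to 300 bases, 0.08 TPM in those of up to 1200 bases and 0.05 TPM in longer ones. Trimming and alignment tools (fastp, cutadapt, HISAT2), DESeq2 and the build TAIR10 are named, per the submitters' processing notes, without versions, roles or the step that made these values. TPM keeps no read depth, so no depth or counting interval is given. The reference in hand was TAIR10.1, which differs from the authors' build, so it was used for gene names, biotypes and the gene lengths above, and no coordinates are printed. Of 32833 genes, 285 were not matched to it, 26633 were above 0 in some library, and 880 had values identical to another gene's.

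Values were analysed as log2(TPM + 1). Genes with at least 1 TPM in at least 3 libraries were kept (20302, of which 19015 are protein-coding) and tested with limma-trend with robust moderation (limma 3.58.1, R 4.3.3), with a mean per group, all 18 libraries in 1 fit and no block, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. The written plan put counts first and gave this test for TPM, and that branch was used because the table holds no counts. All adjusted p-values of single genes come from limma. The 10 comparisons were submergence against air in each line, each mutant against wild type in each condition, and the 3 differences of response (interaction terms). An exact test of 3 libraries against 3 cannot give p under 0.1. The design, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from the alternatives named as added.

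The 21 lists were core hypoxia response, glycolysis, ethylene synthesis and signalling, phytochrome and light signalling, shade avoidance, auxin response, gibberellin metabolism and signalling, abscisic acid metabolism and response, expansins and xyloglucan endotransglucosylases, aquaporins, light harvesting and Rubisco, circadian clock, dark and sugar starvation, phenylpropanoid and anthocyanin synthesis, heat shock and oxidative stress, immune and jasmonate response, and markers of stomatal lineage and guard cells, epidermis and cuticle, vascular tissue, cell division, and root and flower. They held 368 distinct loci, of which 344 were tested and 7 stood in more than 1 list. Each was tested against all tested genes with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Counts of members are given over all genes tested and adjusted over the list alone, and are called positive or negative for differences of response.

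Named genes were PHYA, EIN3, EIL1 and ADH1, and in each comparison the 5 largest positive and 5 largest negative changes among called nuclear protein-coding genes with a symbol, a mean of at least 2 TPM and, except for differences of response, replicates that do not overlap between the groups. Chance alone gives non-overlap in 10% of genes with 3 libraries against 3. The 2 members of smallest adjusted p were added for each list with camera adjusted p under 0.05 (at most 10 lists), and 1 or 2 members for the hypoxia, ethylene, light signalling and shade avoidance lists. For the difference between the phyA-211 and ein3eil1 responses, list members beyond these largest and key genes are not named. AT7SL-1 counts as protein-coding by the reference's biotype.

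The fit was tested on simulated data of 19039 genes, of which 67, 67 and 66 were changed 1.5, 2 and 4 times in submerged phyA-211. For submergence in phyA-211, 20.9%, 70.2% and 98.5% of genes changed 1.5, 2 and 4 times were recovered, with 84 false calls (40% of calls). For phyA-211 against wild type under submergence the shares were 17.9%, 71.6% and 98.5%, with 43 false calls (25.6%). The difference of response of phyA-211 and wild type gave 4.48%, 35.8% and 83.3% with 12 false calls (12.8%), and that of phyA-211 and ein3eil1 gave 5.97%, 35.8% and 89.4% with 16 (15.5%). The threshold of 0.05 was not held in these comparisons. With group-level weights the false shares were 13.6%, 16.7%, 8.24% and 7.5%, and with only the libraries of each comparison 2.38%, 9.64%, 8.82% and 7.27%. The 6 comparisons without submerged phyA-211, simulated without any change, gave at most 1 call.

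The alternatives were median centring and quantile normalization of the log2 values, a pseudocount of 0.1, no filter beyond a nonzero total, a minimum of 5 TPM, only the libraries of each comparison, the replicate number as a block, a required doubling or halving, leaving out each library in turn, an estimated correlation and fry for lists, and an adjusted p under 0.1 for the overlap. Added after seeing the data were group-level library weights, nuclear protein-coding genes alone, submerged phyA-211 replicate 1 alone, and both scalings for the overlap. The overlap of responses was set beside 20 simulations of unchanged mutants that share simulated wild-type libraries, all drawn around wild-type means with independent noise per gene. No library was left out.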

Results

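Leaf messenger RNA was measured in 18 libraries from 4-week-old Arabidopsis thaliana plants of 3 lines: wild type, phyA-211 (a mutant of the far-red light receptor gene PHYA) and ein3eil1 (a double mutant of EIN3 and EIL1, which encode the main transcription factors of the ethylene response). Plants of each line were kept in air or submerged for 6 hours, which makes 6 groups of 3 replicate libraries. The values, in TPM, a length-normalized share of each library, keep no read depth, so no counting interval is given. Each library listed between 20611 and 23189 genes above 0. Of 32833 listed genes, 20302 reached 1 TPM in at least 3 libraries and were tested. Group values are means ± SD (n = 3), and fold changes are differences of mean log2(TPM + 1), which understate the changes of genes with low values. The labels do not say whether replicates came from separate plants or pools, so the adjusted p-values measure the spread between these libraries only.

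The mutated genes were lower in their own lines, except EIN3 under submergence. PHYA stood at 1.2, 1.2 and 1.83 TPM in the 3 phyA-211 air libraries and at 7.5, 10.6 and 12.8 TPM in the 3 submerged ones. Wild type had 11.7 ± 1.32 TPM of PHYA in air and 22.9 ± 0.886 TPM under submergence, and ein3eil1 had 17.5 ± 2.68 and 16.3 ± 3.38 TPM. The fold of phyA-211 against wild type for PHYA was -2.40 in log2 in air (adjusted p = 2.04e-06) and -1.11 under submergence (adjusted p = 0.00105). EIL1 stood at 17, 16.5 and 16.1 TPM in ein3eil1 air and at 11.6, 6.9 and 12.5 TPM in submerged ein3eil1, against 41 ± 2.82 and 67.1 ± 2.21 TPM in wild type. EIL1 in phyA-211 was 48.9 ± 2.50 TPM in air and 92.6 ± 0.901 TPM under submergence. EIN3 stood at 26.9, 27.3 and 28.3 TPM in ein3eil1 air against 59.7 ± 3.37 TPM in wild type (log2 fold change -1.09, adjusted p = 0.0123). Under submergence EIN3 was 42.5, 49.4 and 41.6 TPM in ein3eil1 against 54.5 ± 4.23 TPM in wild type, a log2 difference of -0.29 that did not pass (adjusted p = 0.423), although it passed after median centring (-0.66, adjusted p = 0.0116). In phyA-211, EIN3 was 52.3 ± 13.3 TPM in air and 115 ± 53.5 TPM under submergence. The labels do not say which part of each gene the mutations affect, so a transcript that remains does not show that a functional product was made.

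**Figure D1:**
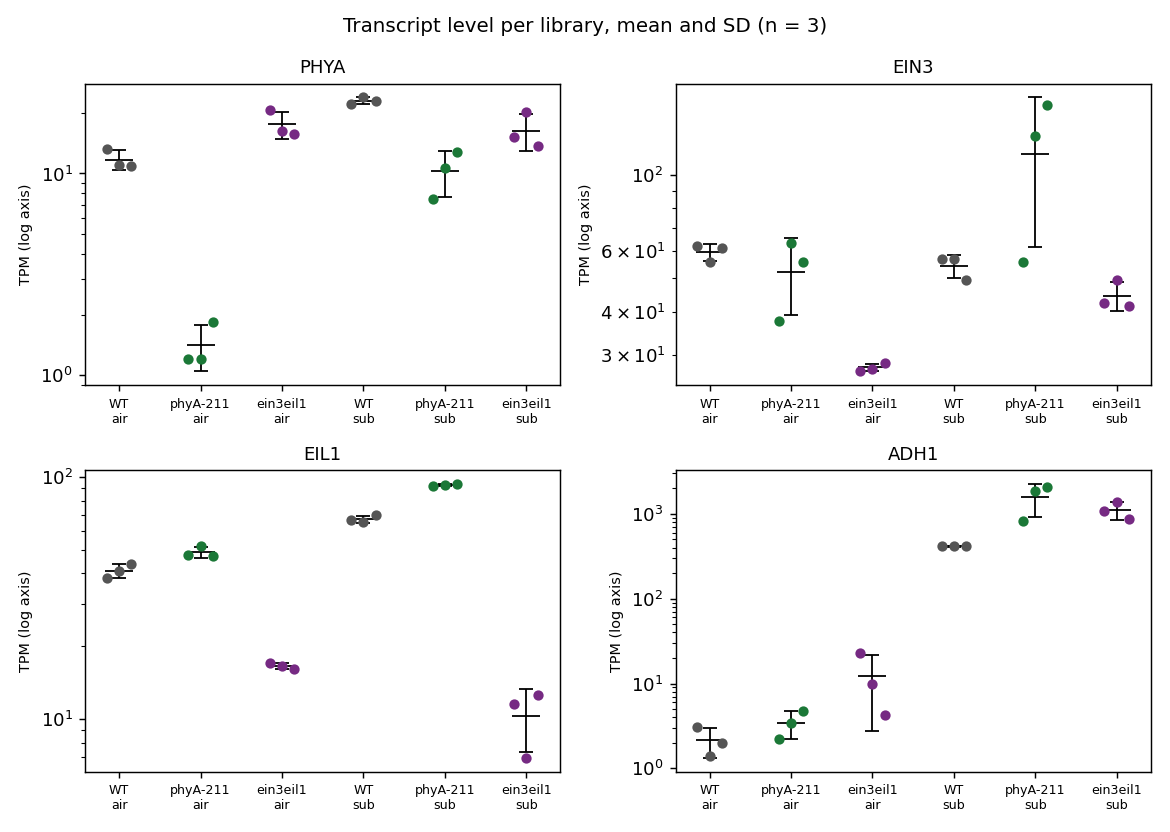
TPM of PHYA, EIN3, EIL1 and ADH1 (log axis) in each of the 18 libraries, with points for libraries and bars for the mean and SD of each group (n = 3). PHYA was lowest in phyA-211 air (1.41 ± 0.364 TPM), EIL1 lowest in submerged ein3eil1 (10.3 ± 3.01 TPM), and ADH1 lay between 412 and 2058 TPM in the submerged libraries.

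Submerged wild-type leaves raised the hypoxia and starvation genes and lowered the anthocyanin and light-harvesting genes. HB1, which encodes a non-symbiotic haemoglobin, rose from 6.22 ± 1.12 to 8097 ± 215 TPM (log2 fold change 10.14, adjusted p = 2.41e-11), and the alcohol dehydrogenase gene ADH1 rose from 2.18 ± 0.852 to 412 ± 1.15 TPM (7.06, adjusted p = 4.38e-09). AT1G33055 was listed at 0 in every wild-type air library and stood at 134 ± 4.92 TPM under submergence. Of the 27 core hypoxia genes tested, 24 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 1.93e-17, adjusted p = 0.079 with an estimated correlation, hereafter estimated). Among dark and sugar starvation genes, 15 of 17 rose and 1 fell, and again 15 and 1 adjusted over the list alone (camera adjusted p = 3.71e-09, estimated 0.092). AT4G35770, a dark-inducible gene, rose from 19.3 ± 5.91 to 2495 ± 93.9 TPM (6.98), and bZIP1, which encodes a factor of sugar signalling, rose from 6.84 ± 1.80 to 89.0 ± 6.60 TPM (3.54).

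Phenylpropanoid and anthocyanin genes fell in wild type: 14 of 16 were called lower, or 15 adjusted over the list alone (camera adjusted p = 9.76e-07, estimated 0.146). LDOX, an enzyme of anthocyanidin synthesis, went from 92.5 ± 42.3 to 0.993 ± 0.196 TPM, and AT1G56650, a MYB regulator of the pathway, was listed at 0 in every submerged library against 53.4 ± 22.4 TPM in air. GSTF12, needed for anthocyanin accumulation, fell by 6.47 on the log2 scale (adjusted p = 1.36e-10). Of 23 light harvesting and Rubisco genes, 19 fell, or 20 adjusted over the list alone (camera adjusted p = 6.35e-05, estimated 0.528). LHCB2.3 fell by 6.31 and LHCB2.1 by 4.75. Abscisic acid genes also fell (13 fell and 1 rose of 17, or 14 and 1 adjusted over the list alone; camera adjusted p = 0.0124, estimated 0.335). AT5G66400 fell by 3.32, while CYP707A3, which encodes an enzyme that degrades the hormone, rose from 2.13 ± 0.490 to 14.3 ± 0.435 TPM. Other genes with the largest falls were CYP79F1, of glucosinolate synthesis, from 146.5 ± 21.2 to 0.933 ± 0.194 TPM, JAL23 from 319 ± 111 to 3.34 ± 0.488 TPM and TLL1 from 277 ± 61.1 to 3.68 ± 0.791 TPM.

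In wild type, ethylene genes rose in 14 of 24 and fell in 2, or 14 and 3 adjusted over the list alone (camera adjusted p = 0.000108, estimated 0.157). ARGOS was at 1.37 ± 0.499 and 58.5 ± 0.347 TPM (4.67) and ARL at 9.76 ± 3.01 and 154 ± 6.78 TPM (3.88). Auxin response genes rose in 9 of 14 and fell in 1, or 10 and 1 adjusted over the list alone (camera adjusted p = 6.69e-05, estimated 0.079). SAUR22 (2.46) and SAUR23 (2.22) rose. Shade avoidance genes rose in 8 of 16 and fell in 2, also adjusted over the list alone (12 and none after median centring, hereafter centred; camera adjusted p = 0.00177, estimated 0.079). YUC5, of auxin synthesis, was at 2.44 and HAT2 at 2.36. Expansin and xyloglucan endotransglucosylase genes rose in 10 of 19 and fell in 2, also adjusted over the list alone (camera adjusted p = 0.00177, estimated 0.286). TCH4 (4.1) and XTH18 (3.93) rose. Phytochrome and light signalling genes went both ways, 5 up and 13 down of 24 (7 and 7 after median centring), with no call for the list (camera adjusted p = 0.709). SPA1 fell by 2.86 and ELIP1 by 3.84, and PHYA itself rose by 0.92 (adjusted p = 0.000734). BT2 (7.68), FTM1 (7.61, from 4.40 ± 7.55 to 483 ± 7.20 TPM) and ORS1 (7.51) were the other genes with the largest rises.

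In wild type 3831 genes were higher and 7719 lower under submergence. The median log2 fold change of all genes was -0.32, and the split depended on scaling: 6539 higher and 4520 lower after median centring, 5297 and 5468 after quantile normalization. The small nuclear RNA genes, which polyadenylated libraries should hold little of, took 0.0383% ± 0.0148 of the TPM total in wild-type air and 0.546% ± 0.042 in submerged wild type.

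Submerged phyA-211 leaves again raised hypoxia, starvation and ethylene genes and lowered flavonoid and light-harvesting genes. All 27 core hypoxia genes rose, also adjusted over the list alone (camera adjusted p = 4.48e-19, estimated 0.0784). HB1 went from 2.65 ± 0.189 to 6632 ± 3465 TPM (10.70, adjusted p = 4.09e-12) and ADH1 from 3.46 ± 1.25 to 1577 ± 659 TPM (8.40, adjusted p = 4.51e-10). AT1G33055 was listed at 0 in phyA-211 air and stood at 393 ± 60.4 TPM under submergence. Starvation genes rose in 14 of 17 and fell in 1, also adjusted over the list alone (camera adjusted p = 1.20e-07, estimated 0.16). The raffinose synthase-like gene DIN10 went from 1.75 ± 1.18 to 1392 ± 603 TPM (8.97) and bZIP1 from 3.19 ± 0.0625 to 101 ± 11.2 TPM (4.60). Ethylene genes rose in 21 of 24 and fell in 1, also adjusted over the list alone (camera adjusted p = 2.89e-07, estimated 0.0933). ARL was at 5.43 and the ethylene receptor gene ETR2 at 5.36.

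All 16 phenylpropanoid genes fell in phyA-211, also adjusted over the list alone (camera adjusted p = 1.21e-11, estimated 0.0814). AT1G56650 changed by -6.81, TT7, a flavonoid hydroxylase, by -4.22, LDOX by -6.07, CHIL by -5.92, UF3GT by -5.60 and GSTF12 by -7.44. All 23 light harvesting and Rubisco genes fell, also adjusted over the list alone (camera adjusted p = 1.21e-11, estimated 0.303). LHCB2.3 went from 1302 ± 536 to 8.69 ± 0.845 TPM and LHCB2.1 from 3093 ± 1238 to 100.2 ± 21.4 TPM. Abscisic acid genes fell in 11 of 17 and rose in 2, also adjusted over the list alone (camera adjusted p = 0.00307, estimated 0.303). AT5G66400 was lower by a log2 change of -4.16 and CYP707A3 higher by 3.08. Aquaporins fell in 11 of 18 and rose in 3, also adjusted over the list alone (camera adjusted p = 0.0309, estimated 0.591). PIP1;4 changed by -2.99 and NIP2;1 by 4.42. Epidermis and cuticle markers fell in 5 of 9, also adjusted over the list alone (camera adjusted p = 0.0309, estimated 0.341). TRY, a trichome patterning gene, was at -3.86 and the lipid transfer gene LP1 at -2.37. Of the light signalling genes, FHL, which acts in the nuclear import of phytochrome A, rose by 2.82 and ELIP1 fell by 4.05. HAT2 (2.72) and YUC5 (3.34) rose among shade avoidance genes, a list with no call (camera adjusted p = 0.146). PHYA rose by 2.21 (adjusted p = 1.07e-07), EIN3 by 1.03 (adjusted p = 0.00589), and EIL1 by 0.91 (adjusted p = 0.000138), although EIN3 did not pass with only these 6 libraries or with submerged phyA-211 replicate 1 alone for its group (adjusted p over the alternatives 3.84e-06 to 0.665). FTM1 (9.76) and ORS1 (8.40) completed the largest rises.

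In phyA-211, 5543 genes were higher and 4845 lower under submergence, with a median of 0.07 over all genes. Replicates of submerged phyA-211 were the most spread of the 6 groups, with a median SD of 0.36 in log2, against 0.10 in submerged wild type. Replicate 1 correlated more with the submerged wild-type libraries (r = 0.957 to 0.96) than with its own replicates 2 and 3 (0.932 and 0.918). With only the 6 libraries of this comparison in the fit, 6451 genes were called. In simulated data with few genes changed 40% of calls were false. Group-level weights gave 7061 genes here.

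In ein3eil1 the hypoxia genes rose and the heat shock genes rose with them. Of 27 core hypoxia genes 26 rose, also adjusted over the list alone (camera adjusted p = 4.27e-22, estimated 0.0472). ADH1 went from 12.4 ± 9.57 to 1110 ± 255 TPM (6.62, adjusted p = 5.89e-09), HB1 from 5.31 ± 3.70 to 5923 ± 1264 TPM (10), ERF71, an ethylene response factor of the hypoxia response, from 0.417 ± 0.442 to 342 ± 111 TPM (7.90), and AT1G33055 from 0.11 ± 0.191 to 151 ± 14.9 TPM (7.10). Of 16 heat shock and oxidative stress genes 15 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 3.56e-10, estimated 0.153). HSP17.6II, a small heat shock protein gene, went from 0.577 ± 0.188 to 251.5 ± 149.8 TPM (7.18), HSFA7A from 3.71 ± 0.861 to 49.1 ± 15.5 TPM (3.38), and HSP17.6A, outside the list, rose by 8. UGT74E2, a glucosyltransferase gene, went from 1.08 ± 0.283 to 622 ± 82.4 TPM (8.23, adjusted p = 1.3e-14).

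Starvation genes rose in 13 of 17 cases and fell in 2 in ein3eil1, also adjusted over the list alone (camera adjusted p = 2.75e-08, estimated 0.153). The autophagy gene ATG8E was at 3.65 and BZO2H3 at 3.2. All 16 phenylpropanoid genes fell, also adjusted over the list alone (camera adjusted p = 1.03e-06, estimated 0.153). AT1G56650 was at -5.89, TT7 at -4.26, GSTF12 at -6.26 and UF3GT at -5.89. Light harvesting genes fell in 20 of 23, or 21 adjusted over the list alone (13 centred; camera adjusted p = 0.000726, estimated 0.534). LHCB2.2 was at -4.55 and LHCB2.1 at -4.27. Auxin response genes rose in 8 of 14 and fell in 1, also adjusted over the list alone (camera adjusted p = 0.000726, estimated 0.153). BRU6, an auxin-conjugating enzyme gene, was at 4.16 and SAUR22 at 1.49. Ethylene genes rose in 9 of 24 and fell in 6, also adjusted over the list alone (14 and 2 centred; camera adjusted p = 0.00762, estimated 0.392). ARL was at 4.85 and ACS7, of ethylene synthesis, at 4.39. Immune and jasmonate genes rose in 9 of 20 and fell in 4, also adjusted over the list alone (9 and 2 centred; camera adjusted p = 0.0168, estimated 0.464). WRKY22 was at 3.92 and WRKY40 at 3.16. Glycolysis genes rose in 5 of 12 and fell in 2, or 6 and 2 adjusted over the list alone (9 and 1 centred; camera adjusted p = 0.0169, estimated 0.534). PFK6 was at 2.00 and HXK1 at -2.77. Expansin and xyloglucan endotransglucosylase genes rose in 7 of 19 and fell in 6, or 8 and 6 adjusted over the list alone (camera adjusted p = 0.0232, estimated 0.451). XTH18 was at 7.86 and XTR6 at 7.49. Circadian clock genes (10 up and 11 down of 25, 11 and 11 adjusted over the list alone, 14 and 4 centred; camera adjusted p = 0.0414, estimated 0.451), shade avoidance genes (4 up and 3 down of 16, 4 and 1 adjusted over the list alone, 8 and 1 centred; camera adjusted p = 0.0421, estimated 0.232) and aquaporins (1 up and 13 down of 18, also adjusted over the list alone; camera adjusted p = 0.0468, estimated 0.553) passed more narrowly. YUC5 (2.21) rose and HB4 (-1.36) fell among the shade avoidance genes, and FHL (1.74) rose and ELIP1 (-2.85) fell among light signalling genes. LBD1 was listed at 0 in submerged ein3eil1 against 32.2 ± 2.04 TPM in air, and TBL26 (-5.20) and SQP1 (-5.09) were the other genes with the largest falls. EIN3 was higher by 0.67 (adjusted p = 0.0457) and EIL1 lower, at -0.67 (adjusted p = 0.00141, called in neither scaling alternative). EIN3 did not pass without a filter, nor without any single one of the 6 libraries (adjusted p from 0.0694 without submerged ein3eil1 replicate 3 to 0.119 without replicate 2).

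In ein3eil1, 3444 genes were higher and 9593 lower under submergence, with a median of -0.48 over all genes; the split was 6186 and 5317 after median centring and 5119 and 6729 after quantile normalization. The PHYA change of -0.11 (adjusted p = 0.64) turned to a called rise of 0.43 after median centring (adjusted p = 0.00622) and 0.37 after quantile normalization (adjusted p = 0.0171). The small nuclear RNA share was 0.0311% ± 0.0056 in ein3eil1 air and 0.483% ± 0.05 in submerged ein3eil1.

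**Figure D2:**
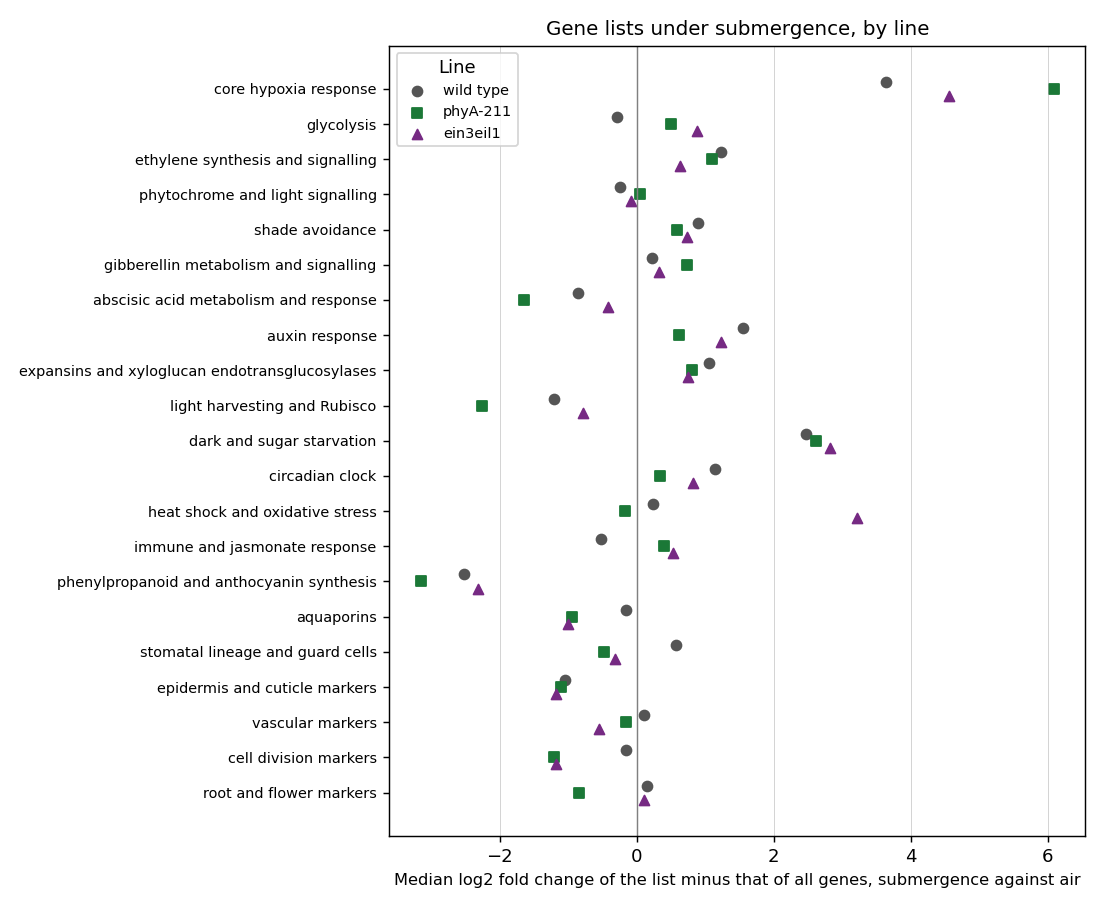
Median log2 fold change of each of the 21 gene lists under submergence minus the median of all genes tested (horizontal axis), with 1 marker per line. The core hypoxia list lay highest in each line (3.64 in wild type, 6.09 in phyA-211 and 4.56 in ein3eil1), and the heat shock list lay at 3.21 in ein3eil1, 0.235 in wild type and -0.17 in phyA-211.

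Air-grown phyA-211 leaves had more transcript of flavonoid genes and less of defence genes than air-grown wild type. The library set weighed below would enter this comparison. Of 16 phenylpropanoid and anthocyanin genes 10 were higher, or 14 adjusted over the list alone (camera adjusted p = 2.20e-16, estimated 0.0461). F3H was 24.3 ± 9.78 TPM in wild type and 100.4 ± 17.5 TPM in phyA-211 (2.06, adjusted p = 0.000664), and TT7 was 14.4 ± 4.37 and 60.7 ± 12.6 TPM (2.02, adjusted p = 3.63e-05). Immune and jasmonate genes were lower in 4 of 20, or 12 adjusted over the list alone (camera adjusted p = 1.18e-06, estimated 0.359). PAD3, of camalexin synthesis, was 120 ± 8.06 and 25.8 ± 18.7 TPM (-2.38), and FRK1, a flagellin-induced kinase gene, was 16.4 ± 2.59 and 2.99 ± 2.33 TPM (-2.27). CYP71A13, also of camalexin synthesis, was lower (-3.12), as were PMT6 (-4.05), KTI1 (-3.55), NIT2 (-3.02) and UPI (-2.81). Starvation genes were lower in 3 of 17, or 7 adjusted over the list alone (camera adjusted p = 4.46e-05, estimated 0.462). DIN10 was at -1.95 and BZO2H3 at -0.90. Heat shock and oxidative stress genes were lower in 3 of 16, or 5 adjusted over the list alone (camera adjusted p = 0.000723, estimated 0.671). RHL41 was at -2.41 and STZ at -1.51, both zinc finger genes. Abscisic acid genes were higher in 3 of 17, or 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00656, estimated 0.462). HAI2 was at 1.78 and COR15A at 1.66. Only 1 of 24 ethylene genes passed, EFE, an ethylene-forming enzyme gene (-0.66), or 2 lower adjusted over the list alone (camera adjusted p = 0.0352, estimated 0.671). ACS6 was 13.6 ± 6.33 against 22.4 ± 4.05 TPM without passing (adjusted p = 0.0769). The calls of EFE, STZ and BZO2H3 were lost in the fit of these 6 libraries alone, that of EFE also after median centring, and those of UPI and COR15A with group-level weights. Calls were lost without wild-type air replicate 1 (COR15A, adjusted p = 0.0868), 2 (UPI 0.0721, DIN10 0.0535, FRK1 0.0525, STZ 0.0694, EFE 0.0774) or 3 (COR15A 0.0654, EFE 0.0956), and phyA-211 air replicate 2 (UPI 0.0586, EFE 0.0564) or 3 (COR15A 0.0831, FRK1 0.0604, EFE 0.091).

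The genes furthest above wild type in phyA-211 air were MRD1 (34.7 ± 9.94 against 0.323 ± 0.307 TPM, 4.75), AT7SL-1 (4.38), LTP3 (4.14), NUDT24 (3.84) and QRT1 (7.36 ± 0.525 against 0.523 ± 0.348 TPM, 2.48). The core hypoxia list (camera adjusted p = 0.215) and the shade avoidance list (camera adjusted p = 0.89) were not called. Their named members did not pass in limma, AT4G24110 standing at -1.10 (adjusted p = 0.0597) and AT3G10020 at -0.62 (adjusted p = 0.122). CKX5 (-0.74, adjusted p = 0.081), YUC8 (-0.43, adjusted p = 0.453) and FHL (0.53, adjusted p = 0.107) did not pass either. Nor did ADH1 (0.48, adjusted p = 0.693), EIL1 (0.25, adjusted p = 0.498) or EIN3 (-0.22, adjusted p = 0.803). In all, 331 genes were higher and 483 lower, and the total of 814 fell to 326 without wild-type air replicate 2, 509 without wild-type air replicate 3 and 390 without phyA-211 air replicate 3, and to 481 with these 6 libraries. The small nuclear RNA share was 1.24% ± 0.698 in phyA-211 air, above the 0.0383% ± 0.0148 of wild-type air.

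Under submergence, phyA-211 had more transcript of hypoxia and glycolysis genes than wild type and less of light-harvesting and auxin genes. Of 27 core hypoxia genes 19 were higher, also adjusted over the list alone (camera adjusted p = 5.45e-07, estimated 0.397). AT3G10040, which encodes a trihelix factor, was 11.4 ± 0.687 TPM in wild type and 217 ± 82.0 TPM in phyA-211 (4.06, adjusted p = 2.66e-06), LBD41 was 74.0 ± 6.08 and 875 ± 86.5 TPM (3.54), and ADH1 was 412 ± 1.15 and 1577 ± 659 TPM (1.83, adjusted p = 0.00701). AT1G33055 was higher by 1.53. Glycolysis genes were higher in 9 of 12, or 11 adjusted over the list alone (5 centred; camera adjusted p = 0.00736, estimated 0.706). FBA6 was at 0.98 and GAPC2 at 0.96. Light harvesting genes were lower in 11 of 23, or 12 adjusted over the list alone (20 centred; camera adjusted p = 6.16e-12, estimated 0.407). CAB2 was at 1344 ± 73.8 and 259 ± 42.3 TPM (-2.38) and CAB3 at 1381 ± 36.5 and 339 ± 23.3 TPM (-2.03).

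Auxin response genes were lower in 5 of 14 and higher in 1, also adjusted over the list alone (camera adjusted p = 0.00251, estimated 0.311). SAUR23 was at -1.33 and IAA29 at -1.29. Shade avoidance genes were lower in 3 of 16 and higher in 2, also adjusted over the list alone (5 and none centred; camera adjusted p = 0.0176, estimated 0.311), with IAA29 and HB-2 (-0.82), a homeodomain factor gene. Expansin and xyloglucan endotransglucosylase genes were lower in 4 of 19 and higher in 3, also adjusted over the list alone (9 and 1 centred; camera adjusted p = 0.00659, estimated 0.407). EXPA1 (1.43) and EXPA10 (1.28), the members with the smallest p, were higher. Stomatal lineage genes (2 lower and 1 higher of 13, also adjusted over the list alone, 6 and none centred; camera adjusted p = 0.0128, estimated 0.407) included STOMAGEN, a promoter of stomatal density, at -1.86, and OST1, a guard cell kinase gene, at 0.41 (-0.06 after median centring). Aquaporins were lower in 2 of 18 and higher in 1, or 1 and 1 adjusted over the list alone (7 lower centred; camera adjusted p = 0.0286, estimated 0.706). PIP2E was at -0.65 and PIP2B at 0.73. FHL was 1.46 and ARL 1.39 higher, and ACS11 was lower, at -1.59. EIN3 was 0.94 higher (adjusted p = 0.0174) and EIL1 0.46 higher (adjusted p = 0.0292), and EIL1 turned to -0.005 after median centring, which also removed the calls of EIN3 (0.47), PIP2B (0.27) and EXPA10 (0.81). The fit of these 6 libraries removed those of EIN3, EIL1, PIP2B, OST1 and SAUR23. PIP2B, EIL1 and OST1 passed in 5 of 10 alternatives. EIN3, PIP2B and OST1 did not pass without wild-type submergence replicate 3 (adjusted p = 0.0576, 0.0729 and 0.0973) or phyA-211 submergence replicate 2 (0.0828, 0.106 and 0.0821) or 3 (0.105, 0.0955 and 0.0882), OST1 without wild-type submergence replicate 1 (0.0654), and EIL1 without any but phyA-211 submergence replicate 1 (0.0587 to 0.0848). MRD1 (6.05), QRT1 (5.15), RLP19 (3.52) and ACR7 (3.23) stood furthest above wild type, and UPI (-3.16), AGP2 (-2.75), GASA1 (-2.53), AGP24 (-2.50) and PRA1.F4 (-2.49) furthest below.

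Between the submerged lines 6639 genes were higher in phyA-211 and 1308 lower, with a median of 0.29 over all genes; the split was 2365 and 4103 after median centring and 2744 and 2271 after quantile normalization. The total of 7947 was 11282 without submerged phyA-211 replicate 1, 3386 without replicate 2, 3122 without replicate 3, 658 with replicate 1 alone and 1368 in the fit of these 6 libraries. Leaving out wild-type submergence replicate 1, 2 or 3 gave 5090, 5208 or 5140. In simulated data with few genes changed 25.6% of calls were false. Group-level weights gave 5306 genes here. ADH1, EIL1, EIN3, UPI, PIP2B, SAUR23, IAA29, ARL, EXPA1, GAPC2, FBA6, STOMAGEN and OST1 did not pass with replicate 1 alone, nor did ADH1 with group-level weights.

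Air-grown ein3eil1 leaves had more transcript of flavonoid genes and vascular markers and less of light-harvesting genes than air-grown wild type. Phenylpropanoid genes were higher in 15 of 16, also adjusted over the list alone (camera adjusted p = 1.91e-08, estimated 0.183). TT7 was at 91.5 ± 2.40 against 14.4 ± 4.37 TPM (2.62, adjusted p = 2.48e-06) and the flavonol regulator MYB111 at 12.9 ± 4.19 against 2.1 ± 0.142 TPM (2.12, adjusted p = 3.75e-05). The defensin genes PDF1.3 (-5.75), PDF1.2c (-5.12), PDF1.2b (-4.72) and PDF1.2 (147 ± 210 against 1512 ± 452 TPM, -4.50), which respond to ethylene and jasmonate, were among the 5 furthest below wild type, with the glycine-rich protein gene GRP9 (-3.92). Light harvesting genes were lower in 14 of 23, or 15 adjusted over the list alone (camera adjusted p = 1.65e-20, estimated 0.183). LHCB2.3 was at -1.76 and CAB3 at -1.30 (not called after quantile normalization). Vascular markers were higher in 11 of 14, or 12 adjusted over the list alone (camera adjusted p = 9.96e-05, estimated 0.294). Among secondary wall genes IRX12 was at 8.22 ± 2.47 against 1.84 ± 0.378 TPM (1.67) and IRX1 at 3.03 ± 0.963 against 0.59 ± 0.138 TPM (1.31). LTP3 (5.16), LTP4 (4.82), CER1, of wax synthesis (3.72), PEL3 (3.3) and the asparaginase gene ASPGB1 (2.90) stood furthest above wild type. PEL3 did not pass without wild-type air replicate 2 (adjusted p = 0.0698) or 3 (0.0667) or ein3eil1 air replicate 1 (0.0611) or 3 (0.0534).

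Auxin response genes were lower in 3 of 14 cases and higher in 2 in ein3eil1 air, or 5 and 2 adjusted over the list alone (5 and none centred; camera adjusted p = 3.81e-05, estimated 0.183). IAA29 was at -2.41 and PIN3, an auxin transporter gene, at 0.56. Starvation genes were lower in 4 of 17 and higher in 1, also adjusted over the list alone (8 and none centred; camera adjusted p = 2.34e-05, estimated 0.269). DIN11 was at -2.25 and AT4G35770 at -1.56. Ethylene genes were lower in 4 of 24 and higher in 4, also adjusted over the list alone (10 lower and none higher centred; camera adjusted p = 0.000118, estimated 0.24). EIL1 was at -1.26 (adjusted p = 0.000165) and ARL at -1.25. Cell division markers were higher in 5 of 6, or 6 adjusted over the list alone, but in none after median centring (camera adjusted p = 0.0401, estimated 0.612). CYC1BAT was at 1.74 and CDKB2;1 at 1.54. Immune and jasmonate genes (1 lower and 2 higher of 20, also adjusted over the list alone, 3 and none centred; camera adjusted p = 0.00432, estimated 0.502) had a median of -0.06 and included WRKY33 at 1.12. Aquaporins (5 higher and 3 lower of 18, also adjusted over the list alone, 1 and 6 centred; camera adjusted p = 0.0172, estimated 0.612) and heat shock genes (2 higher and 1 lower of 16, or 2 and 0 adjusted over the list alone; camera adjusted p = 0.0327, estimated 0.677) tested down while their medians were 0.06 and 0.04 and their means 0.14 and 0.09, since the test is against all genes. PIP2;8 (1.61), PIP2;5 (1.45), STZ (1.51) and DREB2A (1.19) were their members with the smallest p. Among lists with no call, HB4 (1.14), ELIP1 (1.83), ELIP2 (1.45), AT4G24110 (1.34) and AT4G17260 (0.89) were higher. ADH1 was 1.84 higher (adjusted p = 0.00861) and PHYA 0.54 higher (adjusted p = 0.0453), and PHYA was at 0.10 after median centring (adjusted p over the alternatives 0.00467 to 0.602). Both scaling alternatives removed the calls of PHYA, PIN3, PIP2;5, DREB2A, CDKB2;1, CYC1BAT and AT4G17260, quantile normalization those of ADH1 and AT4G24110, and median centring those of WRKY33 and ELIP2. Calls were lost without wild-type air replicate 2 (CDKB2;1, adjusted p = 0.0521, CYC1BAT 0.0547, DIN11 0.0703) or ein3eil1 air replicate 1 (CDKB2;1 0.0545, CYC1BAT 0.0504), and that of PHYA without any but wild-type air replicate 1 (0.064 to 0.165).

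In air 5192 genes were higher in ein3eil1 and 555 lower, with a median of 0.37 over all genes; the split was 823 and 1551 after median centring and 1060 and 1280 after quantile normalization. The total of 5747 was 2353 without wild-type air replicate 2, 3035 without wild-type air replicate 3, and 2579, 3694 and 3486 without ein3eil1 air replicate 1, 2 and 3, but 9687 with these 6 libraries and 10689 with group-level weights.

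Submerged ein3eil1 leaves had more transcript of heat shock and oxidative stress genes than submerged wild type. All 16 heat shock and oxidative stress genes were higher, also adjusted over the list alone (14 centred; camera adjusted p = 2.50e-09, estimated 0.478). HSP18.2 was 3.43 ± 0.221 TPM in wild type and 196.5 ± 156.4 TPM in ein3eil1 (5.20, adjusted p = 5.36e-08), and HSP17.6II was 6.94 ± 1.28 and 251.5 ± 149.8 TPM (4.85). UGT74E2 was 0.69 ± 0.21 and 622 ± 82.4 TPM (8.53, adjusted p = 7.58e-15). AOX1A and AOX1D, which encode mitochondrial alternative oxidases, were 4.84 ± 0.730 against 972 ± 77.7 TPM (7.38, adjusted p = 4.79e-14) and 4.07 ± 1.04 against 973 ± 252 TPM (7.58, adjusted p = 1.9e-10). GSTU9 (7.44) and ABCB11 (6.79) were also among the 5 furthest above wild type. Furthest below were PDF1.3 (-5.93), PDF1.2c (-5.51), PDF1.2b (-5.37), the response regulator gene RR16 (-5.19) and ARGOS, at 1.95 ± 1.33 against 58.5 ± 0.347 TPM (-4.46).

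Ethylene genes were lower in 10 of 24 cases and higher in 6 in submerged ein3eil1, or 11 and 6 adjusted over the list alone (camera adjusted p = 0.0249, estimated 0.558). EIL1 was at -2.62 (adjusted p = 3.82e-09). Auxin response genes were lower in 6 of 14 and higher in 2, also adjusted over the list alone (10 and 2 centred; camera adjusted p = 0.00786, estimated 0.478). IAA29 was at 1.87 ± 1.15 against 32.0 ± 1.75 TPM (-3.60) and BRU6 at 4.31. PAR1, a shade avoidance gene, was 2.3 ± 1.90 against 54.4 ± 2.89 TPM (-4.24) in a list with no call (camera adjusted p = 0.0678). Light harvesting genes were lower in 12 of 23, also adjusted over the list alone (camera adjusted p = 0.000315, estimated 0.558). CAB1 was at -2.05 and LHCB4.2 at -1.30. Glycolysis genes were higher in 8 of 12, also adjusted over the list alone (camera adjusted p = 0.00786, estimated 0.558). GAPC1 was at 1116 ± 248 against 93.7 ± 7.14 TPM (3.54) and PFK3 at 2.54. Core hypoxia genes were higher in 14 of 27 and lower in 2, or 15 and 2 adjusted over the list alone (camera adjusted p = 0.0454, estimated 0.685). AT4G17260, a lactate dehydrogenase gene, was at 2.97 and ERF71 at 2.70. Starvation genes were lower in 6 of 17 and higher in 2, also adjusted over the list alone (camera adjusted p = 0.00786, estimated 0.558). AT4G35770 was at -2.48 and bZIP1 at -1.36. Phenylpropanoid genes were higher in 10 of 16, also adjusted over the list alone (camera adjusted p = 0.00898, estimated 0.558). DFR was at 3.74 and the chalcone synthase gene TT4 at 2.55. Immune and jasmonate genes were higher in 12 of 20 and lower in 2, also adjusted over the list alone (camera adjusted p = 0.0307, estimated 0.558). EDS16, of salicylic acid synthesis, was at 308 ± 80.2 against 8.83 ± 0.673 TPM (4.95) and WRKY33 at 2.06. Abscisic acid genes were higher in 8 of 17, or 9 adjusted over the list alone (camera adjusted p = 0.0327, estimated 0.558). COR15A was at 3.08 and CYP707A3 at 1.54. HYH (1.84) and ELIP1 (2.83) were higher among light signalling genes, ADH1 was 1.4 higher (adjusted p = 0.0166) and PHYA was lower, at -0.49 (adjusted p = 0.0482).

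Between the submerged lines 5781 genes were higher in ein3eil1 and 3257 lower, with a median of 0.19 over all genes; the split was 3835 and 6116 after median centring and 4006 and 5542 after quantile normalization. PHYA did not pass with a pseudocount of 0.1, no filter or the block, nor without any single one of 5 of the 6 libraries (adjusted p from 0.0834 without wild-type submergence replicate 1 to 0.169 without ein3eil1 submergence replicate 3), and ADH1 did not pass without ein3eil1 submergence replicate 2 (adjusted p = 0.0689).

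**Figure D3:**
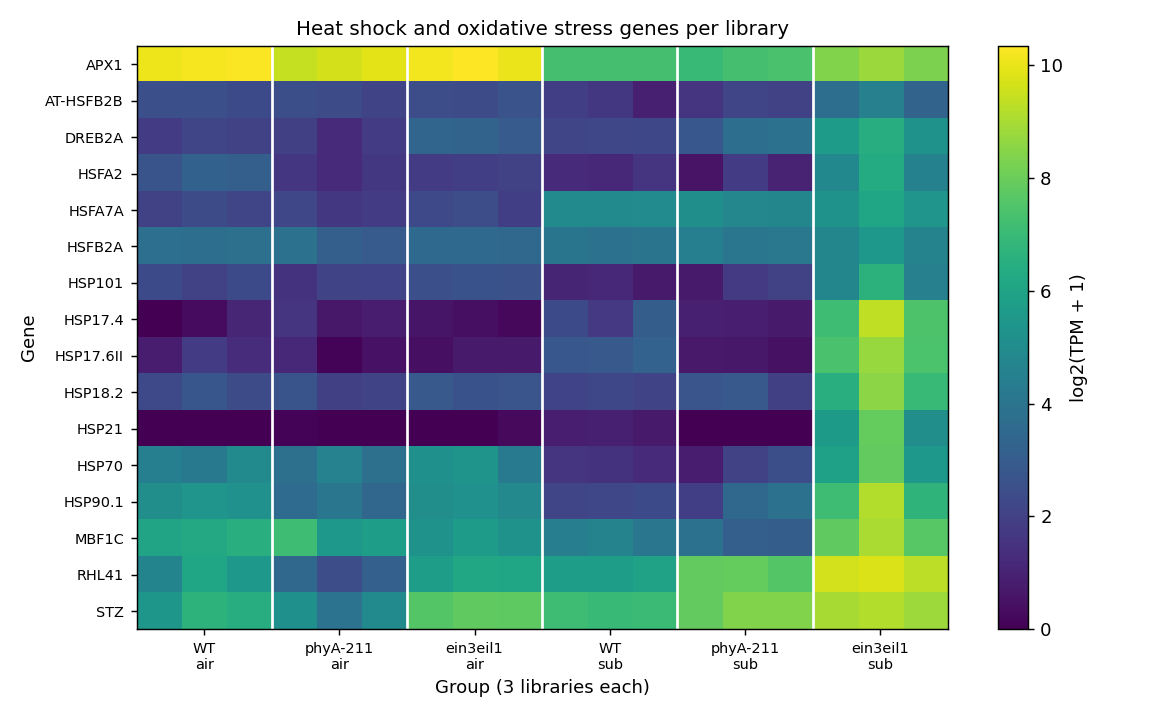
Heat map of log2(TPM + 1) for the 16 heat shock and oxidative stress genes (vertical) in the 18 libraries (horizontal, 3 per group). All 16 genes were higher in submerged ein3eil1 than in submerged wild type (14 after median centring), by a median of 3.86 in log2.

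The response to submergence itself differed between phyA-211 and wild type, with the change of hypoxia genes larger in phyA-211. The library set weighed below would enter this difference and that of phyA-211 and ein3eil1. The difference of response was positive for 18 of 27 core hypoxia genes, or 19 adjusted over the list alone (12 centred; camera adjusted p = 3.84e-07, estimated 0.296). It was 4.33 for AT4G24110 (adjusted p = 3.9e-05) and 4.17 for AT3G10040 (adjusted p = 0.00019). ADH1 did not pass (1.34, adjusted p = 0.111). Ethylene genes were positive in 13 of 24 and negative in 1, or 16 and 1 adjusted over the list alone (4 and 2 centred; camera adjusted p = 0.00869, estimated 0.474). ETR2 was at 2.03 and ARL at 1.55. Glycolysis genes were positive in 7 of 12, or 9 adjusted over the list alone (1 centred; camera adjusted p = 0.00318, estimated 0.68). iPGAM1 was at 1.39 and FBA6 at 1.19. The negative lists were light harvesting (6 of 23, also adjusted over the list alone; camera adjusted p = 1.31e-06, estimated 0.565). CAB2 was at -1.94 and CAB3 at -1.74. Also negative was phenylpropanoid synthesis (5 of 16, or 6 adjusted over the list alone, 9 centred; camera adjusted p = 1.64e-05, estimated 0.296). MYB111 was at -1.69 and TT7 at -1.43. Auxin response (4 negative and 1 positive of 14, or 5 and 1 adjusted over the list alone; camera adjusted p = 0.0018, estimated 0.296), stomatal lineage (2 of 13, also adjusted over the list alone, 6 centred; camera adjusted p = 0.00318, estimated 0.32) and shade avoidance genes (2 negative and 1 positive of 16, also adjusted over the list alone; camera adjusted p = 0.0483, estimated 0.296) followed. SAUR23 was at -1.69, SAUR22 at -1.27, STOMAGEN at -2.43, EPF2 at -1.96, IAA29 at -1.50 and HB-2 at -0.69. PHYA (1.29, adjusted p = 0.00847), SPA1 (1.43) and EIN3 (1.16, adjusted p = 0.0447) were positive, and EIL1 did not pass (0.21, adjusted p = 0.474; -0.33 after median centring). EIN3 passed in neither scaling alternative, nor FBA6 after median centring. Calls were also lost with these 12 libraries alone (EIN3, SPA1, HB-2, EPF2), no filter (EIN3, EPF2), group-level weights (HB-2) or a pseudocount of 0.1 (IAA29). With submerged phyA-211 replicate 1 alone only AT4G24110, AT3G10040, MYB111 and TT7 of these genes passed. With 1 library left out EIN3 passed only without phyA-211 air replicate 2 or submergence replicate 1 (otherwise adjusted p = 0.06 to 0.122) and EPF2 only without these or wild-type air replicate 1 (0.0637 to 0.101). HB-2 was lost without wild-type air replicate 1, wild-type submergence replicate 1 or 3 or phyA-211 submergence replicate 3 (0.0502 to 0.0644), IAA29 without wild-type submergence replicate 1 or phyA-211 submergence replicate 2 or 3 (0.0506 to 0.0584), SPA1 without phyA-211 submergence replicate 2 (0.0609) or 3 (0.0561) and SAUR22 without the latter (0.0506).

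The genes with the largest differences between the phyA-211 and wild-type responses were NUDT21 (4.81), PMT6 (4.76), RHL41 (4.36) and LBD41 (3.93) above, and AT7SL-1 (-4.42), LTP3 (-3.65), LSU1 (-3.17) and GER3 (-3.14) below. ATL6 and NUDT24, also in these sets, were listed at 0 in submerged wild type. PMT6, AT7SL-1, LTP3, NUDT24 and RHL41 differed the other way in air, which makes up most of their differences. LTP3, LSU1, GER3, LBD41 and ATL6 did not pass with submerged phyA-211 replicate 1 alone, nor LTP3 with group-level weights. With 1 library left out LTP3 passed only without wild-type air replicate 3, phyA-211 air replicate 2 or phyA-211 submergence replicate 1 (otherwise adjusted p = 0.0503 to 0.0776), and ATL6 failed without phyA-211 submergence replicate 3 (0.0541). In all 4140 genes were positive and 850 negative, with a median of 0.35 over all genes; the split was 1219 and 2369 after median centring and 1433 and 1336 after quantile normalization. The total of 4990 was 10311, 1092 and 1379 without submerged phyA-211 replicate 1, 2 and 3. It was 1787, 2916 and 2835 without wild-type air replicate 1, 2 and 3, 2491 and 3081 without phyA-211 air replicate 1 and 3, 1837, 1957 and 1843 without wild-type submergence replicate 1, 2 and 3, and 1790 in the fit of these 12 libraries. The simulated false share was 12.8%.

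The ein3eil1 response differed from that of wild type in the heat shock genes. Their difference of response was positive in 14 of 16, also adjusted over the list alone (14 centred; camera adjusted p = 1.07e-14, estimated 0.247). It was 5.51 for HSP17.6II (adjusted p = 1.38e-06) and 5.01 for HSFA2, a heat shock factor gene. Immune and jasmonate genes were positive in 8 of 20, or 11 positive and 1 negative adjusted over the list alone (camera adjusted p = 0.000173, estimated 0.801). EDS16 was at 3.98 and LOX2, of jasmonate synthesis, at 2.84. Glycolysis genes were positive in 6 of 12 and negative in 1, also adjusted over the list alone (camera adjusted p = 0.00266, estimated 0.934). GAPC1 was at 3.67 and PFK3 at 1.80. Core hypoxia genes passed narrowly (5 positive and 1 negative of 27, also adjusted over the list alone; camera adjusted p = 0.0458, estimated 0.934). ERF71 was at 2.49 (1.9 and not called with a pseudocount of 0.1) and AT4G17260 at 2.09. UGT74E2 (7.97), AOX1D (7.61), GSTU9 (6.99) and AOX1A (6.89) were furthest above, with ATL6, listed at 0 in submerged wild type, and GER3 (-4.30), ORS1 (-4.25), ARGOS (-3.92), PAR1 (-3.89) and ADS4 (-3.72) furthest below. Among lists with no call, RTE1, a regulator of an ethylene receptor, was negative at -1.88, as were PIF3 (-1.78) and HAT2 (-1.13), and HYH was positive at 1.52. PHYA (-1.02, adjusted p = 0.0102) and EIL1 (-1.37, adjusted p = 0.000332) were negative, and ADH1 (-0.44, adjusted p = 0.647) and EIN3 (0.80, adjusted p = 0.147) did not pass. PHYA rose in wild type and had no call in ein3eil1, but was called higher there after median centring (0.428) and quantile normalization (0.369). EIL1 rose in wild type and fell in ein3eil1, a fall called in neither scaling alternative. In all 2192 genes were positive and 3379 negative, with a median of -0.20 over all genes; the split was 2659 and 2656 after median centring and 2538 and 2773 after quantile normalization.

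Set directly against each other, the phyA-211 and ein3eil1 responses parted in the heat shock genes, negative in 11 of 16 and positive in 2, also adjusted over the list alone (camera adjusted p = 2.79e-11, estimated 0.492). UGT74E2 (-8.15), HSP17.4 (-7.72), AOX1A (-7.62), HSP17.6A (-7.50) and LSU1 (-7.42) were furthest below, and ORS1 (5.13), PMT6 (4.80), CBF2 (4.28), BGAL1 (4.22) and ARGOS (4.11) furthest above. Light harvesting (7 negative of 23, also adjusted over the list alone; camera adjusted p = 1.30e-06, estimated 0.77), immune and jasmonate (4 negative and 2 positive of 20, also adjusted over the list alone, 8 and 2 centred; camera adjusted p = 0.022, estimated 0.77) and phenylpropanoid genes (4 negative and 1 positive of 16, or 3 and 1 adjusted over the list alone; camera adjusted p = 0.0444, estimated 0.77) also passed. The last list had a median of 0.01 and a mean of -0.28. PHYA (2.32, adjusted p = 1.77e-05), EIL1 (1.58, adjusted p = 9.2e-05) and ADH1 (1.78, adjusted p = 0.0287) were positive, and EIN3 did not pass (0.36, adjusted p = 0.473; -0.25 after median centring). In all 7655 genes were positive and 1790 negative, with a median of 0.545 over all genes; the split was 2436 and 3376 after median centring and 3541 and 2590 after quantile normalization. With replicate 1 alone for submerged phyA-211 the total of 9445 was 5289. The simulated false share was 15.5%. ADH1 passed in 5 of 10 alternatives (1.17 after median centring), and did not pass without air replicate 1 of either line, phyA-211 submergence replicate 2 or 3 or ein3eil1 submergence replicate 1 or 3 (adjusted p = 0.051 to 0.0734).

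The differences of response of the mutants overlapped. Of the 4140 genes positive in phyA-211 and 2192 in ein3eil1, 670 were shared (447 for independent lists), and of 850 and 3379 negative genes 400 were shared (141.5 for independent lists), while 159 and 38 went opposite ways. Across genes, which are not independent replicates, the log2 differences had Pearson's r of 0.365 and Spearman's rho of 0.413. Both differences use the same wild-type libraries, and unchanged mutants simulated against those libraries gave a mean r of 0.431 (lowest 0.381) and rho of 0.374. They had at most 2 calls in a direction, so they give no value for shared calls. The covariance was 0.343 against 0.0925 simulated. With 3 wild-type libraries per condition the controls cannot be split into parts of at least 2, so part of the excess of shared genes may come from the shared libraries.

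Markers of other leaf cell types had few list calls under submergence. Vascular markers fell in 3 of 14 cases in wild type and 11 in ein3eil1 (2, with 3 rising, and 7, with 1 rising, centred), cell division markers in 4 of 6 in phyA-211 and 5 in ein3eil1 (4 and 4 centred), and epidermis and cuticle markers in 6 of 9 in wild type and 7 in ein3eil1 (adjusted over the list alone, 2 vascular markers in wild type and otherwise the same). Stomatal lineage and guard cell genes, which rose in 2 and fell in 4, 4 and 6 of 13 cases (centred, rose in 7, 2 and 3 and fell in 2, 4 and 5), had no list call (camera adjusted p = 0.472 in wild type, 0.168 in phyA-211 and 0.79 in ein3eil1), nor had vascular markers (0.826, 0.662 and 0.0724), cell division markers (0.826, 0.216 and 0.2) or root and flower markers (0.826, 0.647 and 0.568). Gibberellin genes rose in 3 of 15 cases and fell in 5 in wild type, also adjusted over the list alone, and rose in 8 and fell in 1 after median centring (camera adjusted p = 0.478), and the list was called in none of the 10 comparisons. Of the 80 list calls among 210 tests, 2 held with an estimated correlation: core hypoxia genes in submerged ein3eil1 and phenylpropanoid genes in phyA-211 air. The defensin genes (PDF1.2, PDF1.2b, PDF1.2c), the light-harvesting genes (CAB1, CAB2, CAB3, LHCB2.1, LHCB2.2) and the SAUR genes have near-identical copies, so the division of reads among the members of each family is uncertain.

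**Figure D4:**
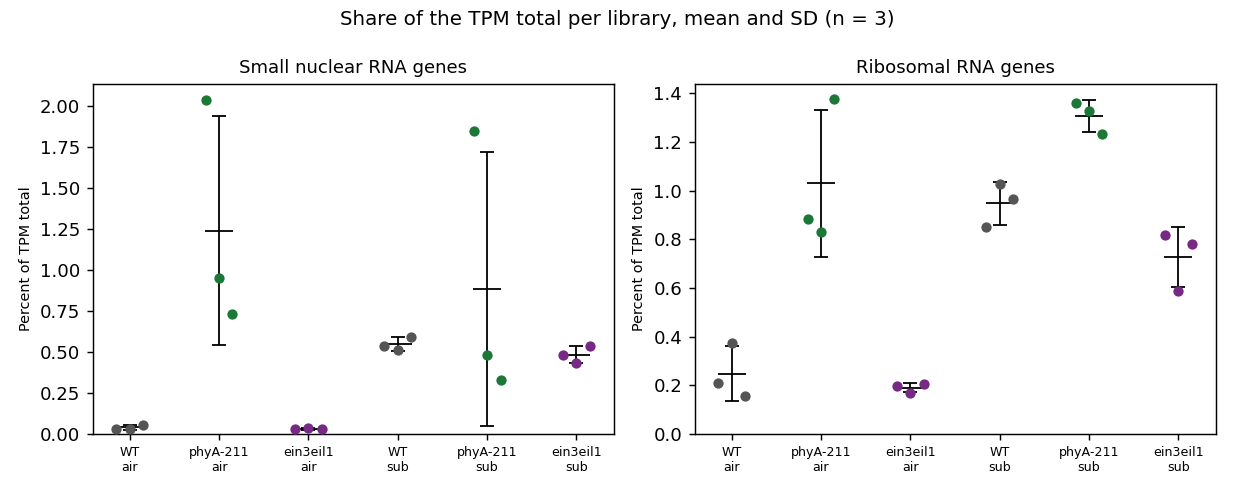
Share of each library's TPM total taken by genes annotated as small nuclear RNA (left) and ribosomal RNA (right), in percent, with points for libraries and bars for mean and SD (n = 3). Small nuclear RNA lay between 0.0277% and 0.0553% in the air libraries of wild type and ein3eil1 and between 0.329% and 2.04% in the other 12 libraries.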

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

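Chosen only after the result was seen were the scaling and small nuclear RNA tests of the heat shock pattern, the submergence and library-set tests of the small nuclear RNA pattern, and both PHYA tests reported here. Of the PHYA tests, only the bounds of the wild-type RNA test were written before its value was known. The results below differ between lines by the test of the difference of response, and the values of genes and list medians are log2 differences. Over all genes the median difference was 0.35 between phyA-211 and wild type, -0.20 between ein3eil1 and wild type and 0.545 between phyA-211 and ein3eil1, and the splits into higher and lower depended on scaling.

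Between phyA-211 and wild type, the difference of response was positive for 4140 genes and negative for 850. In the fit of those 12 libraries the real grouping gave 1790 genes. Of 100 drawn splits only the real one gave as many, and the highest other gave 1688. That split exchanged the line labels in 1 condition only, which turns the contrast into the difference between lines over both conditions. Other splits mix lines within groups, so here and below the splits cannot decide whether responses differ. Median centring gave 1219 positive and 2369 negative. The total of 4990 ranged from 1092 to 10311 with 1 library left out. The list medians were 1.94 for core hypoxia, 1.14 for glycolysis, 1.165 for ethylene, -0.13 for shade avoidance, -0.63 for auxin response, -0.57 for light harvesting, -0.95 for phenylpropanoid synthesis and -0.33 for stomatal lineage genes. EIN3 (1.16), PHYA (1.29), NUDT21 (4.81), LBD41 (3.93), PMT6 (4.76), RHL41 (4.36), AT3G10040 (4.17), AT4G24110 (4.33), ARL (1.55), ETR2 (2.03), iPGAM1 (1.39), FBA6 (1.19) and SPA1 (1.43) were positive. LSU1 (-3.17), AT7SL-1 (-4.42), GER3 (-3.14), LTP3 (-3.65), SAUR22 (-1.27), SAUR23 (-1.69), CAB3 (-1.74), CAB2 (-1.94), TT7 (-1.43), MYB111 (-1.69), HB-2 (-0.69), IAA29 (-1.50), EPF2 (-1.96) and STOMAGEN (-2.425) were negative. ATL6 (5.68) and NUDT24 (-3.62) were listed at 0 in submerged wild type, so their differences depend on the pseudocount.

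Between ein3eil1 and wild type, the difference of response was positive for 2192 genes and negative for 3379. The real grouping of those 12 libraries gave 8278 genes. Of 100 drawn splits 2, the real one included, gave as many. The highest other split gave 13108 genes and exchanged the line labels in 1 condition only, which points to the large difference between these lines as a structure of the samples. Median centring gave 2659 positive and 2656 negative. The list medians were 0.11 for core hypoxia, 0.69 for glycolysis, 4.27 for heat shock and 1.24 for immune and jasmonate genes. UGT74E2 (7.97), AOX1D (7.61), AOX1A (6.895), GSTU9 (6.99), ERF71 (2.49), AT4G17260 (2.09), GAPC1 (3.67), PFK3 (1.80), HSFA2 (5.01), HSP17.6II (5.51), EDS16 (3.98), LOX2 (2.84) and HYH (1.52) were positive. PHYA (-1.025), EIL1 (-1.37), ADS4 (-3.72), ORS1 (-4.25), GER3 (-4.30), ARGOS (-3.92), PAR1 (-3.89), RTE1 (-1.88), PIF3 (-1.78) and HAT2 (-1.13) were negative. ATL6 (8.43) was listed at 0 in submerged wild type, so its difference depends on the pseudocount, as did the call of ERF71.

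Between phyA-211 and ein3eil1, the difference of response was positive for 7655 genes and negative for 1790. The real grouping of those 12 libraries gave 6793 genes, and 1 of 100 drawn splits, the real one, gave as many. The highest other, which kept all 3 air labels and 2 of 3 submergence labels of phyA-211, gave 6157. Median centring gave 2436 positive and 3376 negative. The list medians were -0.54 for light harvesting, -3.16 for heat shock, -0.22 for immune and jasmonate and 0.011 for phenylpropanoid genes. ADH1 (1.78), EIL1 (1.58), PHYA (2.32), ORS1 (5.13), BGAL1 (4.22), CBF2 (4.28), PMT6 (4.80) and ARGOS (4.11) were positive, and UGT74E2 (-8.15), AOX1A (-7.62), LSU1 (-7.42), HSP17.6A (-7.50) and HSP17.4 (-7.72) were negative.

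The 7 comparisons of 3 libraries against 3 make 10 splits each, too few for a share under 0.05. In fits of their own libraries the real grouping and the highest other split gave 13912 and 1 genes for submergence in wild type, 6451 and 1 in phyA-211 and 13748 and 0 in ein3eil1. The counts were 481 and 6 for phyA-211 against wild type in air, 1368 and 2 under submergence, 9687 and 2 for ein3eil1 against wild type in air and 11213 and 1 under submergence.

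The heat shock and oxidative stress genes were higher in submerged ein3eil1 than in submerged wild type in 16 of 16 cases. Scaling alone does not account for it, since 14 members were called after median centring, and neither does 1 library, since at least 15 were called whichever submerged ein3eil1 library was left out. The small nuclear RNA share of the libraries is argued against by phyA-211 and wild type in air, which differ in that share while the list had a median of -0.397. A response of the ein3eil1 line to submergence stays open as a hypothesis, as do differences in handling or heat between the groups, which no label records.

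The small nuclear RNA share was high in phyA-211 air and in every submerged group. Submergence alone is argued against by the phyA-211 air libraries, of which the lowest had 0.7305%. A separate library preparation or sequencing set may be involved, since ribosomal RNA was also at most 0.373% in the low libraries and at least 0.586% in the others, and protein-coding genes at least 97.57% and at most 96.17%, compared afterwards. Small nucleolar RNA did not split the same libraries (gap -0.0012 percentage points), no label gives a set and the split follows whole groups, so this cannot be told apart from the groups. Displacement of other genes' TPM did not make the calls, since nuclear protein-coding genes alone, rescaled, moved the counts by at most 0.1181 in log2 over the 10 comparisons.

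PHYA stood at 32.7%, 46.3% and 55.6% of submerged wild type in the 3 submerged phyA-211 libraries, of which replicate 1 correlated more with submerged wild type than with replicates 2 and 3. First versions of both tests were run and did not decide: of 18 genes low in phyA-211 air, 2, 3 and 5 lay under 0.5 times the level a wild-type share would bring against a bound of 3, and 53.9%, 38.5% and 41% of 39 line genes lay above submerged wild type against bounds of 25% and 75%. The versions reported were chosen afterwards. Another line's library under this label is argued against, since at least 135 genes abundant in submerged wild type or ein3eil1 lay under 0.5 times that line's lowest library, against at most 34 for a library of the same line. For wild-type RNA at the PHYA share, 11, 30 and 75 of 5584 abundant genes lay under 0.5 times the level it would bring. Single wild-type libraries had 0, 6 and 1 under 0.5 times the others. The bound of 100, set before the value was seen, was not met, so it is not excluded.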

How the results depend on the processing

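Settings added after the data were seen are named with the processing above. Counts of called genes stayed within 1.5 times in all 10 comparisons with a pseudocount of 0.1, no filter, a minimum of 5 TPM, nuclear protein-coding genes alone and the replicate block. The TPM values hold no counts, so the planned DESeq2 size factors, upper-quartile factors and DESeq2 Wald test were not run, and what depth limits cannot be given. Where a count moved, the cause was not tested, except that a required doubling or halving can only remove calls.

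With only the libraries of the comparison the counts were 6451 for submergence in phyA-211, 481 for phyA-211 against wild type in air, 1368 under submergence, 9687 for ein3eil1 against wild type in air and 1790 for the phyA-211 minus wild type difference of response. Median centring gave 2374 for ein3eil1 against wild type in air and 5812 for the phyA-211 minus ein3eil1 difference. Quantile normalization gave 5015 for phyA-211 against wild type under submergence, 2340 for ein3eil1 against wild type in air, 2769 for the phyA-211 minus wild type difference and 6131 for the phyA-211 minus ein3eil1 difference. Group-level weights gave 10689 for ein3eil1 against wild type in air and 8428 for the ein3eil1 minus wild type difference. Submerged phyA-211 replicate 1 alone gave 658 for phyA-211 against wild type under submergence, 255 for the phyA-211 minus wild type difference and 5289 for the phyA-211 minus ein3eil1 difference. That lone library is assumed to vary like the other groups.

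With a required doubling or halving, submergence gave 6215 genes in wild type, 5613 in phyA-211 and 7725 in ein3eil1. The same setting gave 539 for phyA-211 against wild type in air and 2816 under submergence, 1689 and 4440 for ein3eil1 against wild type, and 3700 and 6231 for the ein3eil1 minus wild type and phyA-211 minus ein3eil1 differences. Leaving out 1 library at a time gave 9833 to 10663 genes for submergence in wild type, 9072 to 12119 in phyA-211 and 11687 to 12385 in ein3eil1. The ranges were 326 to 985 and 3122 to 11282 for phyA-211 against wild type in air and under submergence, and 2353 to 4607 and 6986 to 8315 for ein3eil1. For the differences they were 1092 to 10311 (phyA-211 minus wild type), 4429 to 5221 (ein3eil1 minus wild type) and 7536 to 11788 (phyA-211 minus ein3eil1).

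Of 210 list tests 80 were called, 2 with an estimated correlation, 106 with fry and 80 with the replicate block. Direction and side of the threshold were as reported in 132 of the 210 with an estimated correlation, 138 with fry and 208 with the block. The overlap of responses was 1070 genes, 1961 at an adjusted p under 0.1, 1188 after median centring and 956 after quantile normalization. PHYA in ein3eil1 under submergence turned from -0.11 to 0.369 with quantile normalization and 0.428 with median centring, both called as rises. Between submerged phyA-211 and wild type median centring turned EIL1 to -0.005 and OST1 to -0.058. Of 316 checks of named genes 288 kept direction and side of the threshold with median centring, 293 with quantile normalization, 301 with only the libraries of the comparison, 305 with weights, 311 with a pseudocount of 0.1, 311 with no filter, 314 with the block and 316 with protein-coding genes alone. With a minimum of 5 TPM 310 of 310 did, and with submerged phyA-211 replicate 1 alone 83 of 120. Of 2400 checks of named genes with 1 library left out, 2293 kept direction and side of the threshold, 99 lost the call, 5 gained it and 3 moved.

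Over all groups the replicate numbers did not pair the samples. Deviations of same-number libraries from group means correlated between -0.375 and 0.438, over 0.1 in 7 of 45 pairs. The own number was highest in 29 of 90 comparisons and in every other group for 0 of 18 libraries. Between air and submergence r was 0.438, 0.201 and 0.09 in phyA-211, where pairing stays open, and at most 0.089 in the other lines. With the replicate block the counts were 3756 higher and 7543 lower for submergence in wild type, 5432 and 4747 in phyA-211 and 3379 and 9477 in ein3eil1. PHYA in ein3eil1 against wild type had an adjusted p of 0.0618 in air and 0.0669 under submergence with the block (over the alternatives 0.00467 to 0.602 in air and 3.71e-05 to 0.169 under submergence).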

Other observations

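The gene families below were chosen after the data were seen, and the mitochondrial test was planned before its values were known. Ribosomal protein genes rose under submergence in wild type in 179 of 299 cases and fell in 21 (224 and 3 after median centring; camera adjusted p = 1.16e-17, estimated 0.405). Their difference of response between ein3eil1 and wild type was negative in 158 cases and positive in 2 (73 and 2 after median centring; camera adjusted p = 9.35e-15, estimated 0.481). SAUR-like genes rose in 37 of 62 cases and fell in 2 in wild type (44 and 2 after median centring; camera adjusted p = 1.38e-11, estimated 0.405), and were lower in submerged ein3eil1 than in submerged wild type in 33 cases and higher in 2 (41 and 2 after median centring; camera adjusted p = 9.11e-10, estimated 0.53).

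Immune receptor genes of the TIR-NBS-LRR family were higher than in submerged wild type in 48 of 72 cases and lower in 2 in submerged phyA-211 (25 and 4 after median centring; camera adjusted p = 0.000155, estimated 0.656). In submerged ein3eil1 they were higher in 58 cases (52 higher and 2 lower after median centring; camera adjusted p = 1.48e-10, estimated 0.541). For glutathione transferase genes the difference of response between phyA-211 and ein3eil1 was negative in 20 of 38 cases and positive in 4 (23 and 2 after median centring; camera adjusted p = 9.56e-14, estimated 0.0536): 7 rose and 19 fell in phyA-211, and 18 rose and 12 fell in ein3eil1. WRKY factor genes were lower in phyA-211 air than in wild-type air in 13 of 57 cases and higher in 1 (12 and 1 after median centring; camera adjusted p = 3.52e-11, estimated 0.739). In all 16 families were tested in 160 comparisons, and these genes have near copies that can share reads. Quantile normalization was not tried for families.

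AOX1A and UGT74E2, among the genes furthest above wild type in submerged ein3eil1, are generally counted among targets of the mitochondrial dysfunction response, which raised the hypothesis that this response was active there. A further 7 members (AT2G21640, AT5G09570, BCS1, NDB2, NDA2, NAC13 and AT5G51440) were listed from general knowledge before their values were seen, and 7 of 7 were called higher than in submerged wild type, also after median centring. Of these, NDA2 hardly differed between air and submergence in ein3eil1 (46.1 and 46.5 TPM, against 38 and 15.4 TPM in wild type), and NDB2 was at 23.1 and 28.8 TPM (25.6 and 1.09 TPM in wild type). Of all 20302 genes 5781 were called higher there, or 3835 after median centring. NAC13, a regulator of that response, was 109 ± 11.1 TPM in submerged ein3eil1 against 3.56 ± 0.234 TPM in submerged wild type (log2 fold change 4.59, adjusted p = 2.58e-12), BCS1 was 428 ± 62.7 against 18.5 ± 1.5 TPM (4.45), and AT5G51440 was 348 ± 187.5 against 5.09 ± 0.669 TPM (5.72). AT2G21640 (4.65), NDB2 (3.78), AT5G09570 (2.05) and NDA2 (1.54) were the other 4. Other stresses raise these genes too, so a mitochondrial response may be 1 of several.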
